A study of Mus musculus with 5 samples.

How the data were processed

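Gene expression was measured in total RNA from uteri of mice aged 15 days on a mixed C57BL/6J;129S5/Brd background. The cKO mice carried a deletion of Dicer, the enzyme that cuts microRNA precursors into mature microRNAs, made with Cre recombinase expressed from the progesterone receptor locus (PR-Cre). Per the labels, each sample was a pool of uteri hybridised as biotin-labelled RNA to 1 Illumina bead array: 3 control pools (7, 9 and 11) and 2 Dicer cKO pools (10 and 12). How many uteri made up a pool is not given in the sources used here, so the p-values measure the spread between these pools. The labels name a human WG-6 v3 BeadChip, while the gene names of the files, written in capitals, match mouse genes, many of them known only from mouse cDNA collections; the gene names of the files were used.

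The authors deposited, for each array, a mean bead intensity per probe on a linear scale, and per the submitters' processing notes BeadStudio (version not stated) was the software. The deposited intensity values had not been background-subtracted or normalized between arrays, as the values themselves show: the lowest intensity lay between 27.9 and 29.5, and the array medians ran from 57.5 to 63.0. The deposited detection score ran from 0 to 1 and rose with signal, so 1 minus the score was used as the detection p. Per the file headers, the files also held the SD of the bead intensities and the number of beads per probe, with a median of 44 beads on every array. A further table of the whole series held an intensity per probe that the authors had quantile-normalized on a linear scale, as judged from the values: every column had a median of 71.1 and a maximum of 44606.2. Its row identifiers could not be matched to the probes of the array files, so its rows were not named, and it served only for a count of probes. Its direction and centring follow from the linear intensity scale. Its lowest value, 30.5 in every column, lay near the lowest intensities of the array files, which argues against a background subtraction. Any other background treatment stays unknown.

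From the array files, normexp background correction from the detection p values with an offset of 16, quantile normalization and log2 transformation were done with the neqc function of limma 3.58.1 in R 4.3.3. Of 45281 probes, the 22845 with a detection p under 0.05 on at least 2 of the 5 arrays, counted without regard to group, were kept. Array names were brought to current symbols with a RefSeq gene table of assembly GRCm38.p6, used for names and for which genes neighbour each other. Of all probes, 22864 carried a current symbol, 11917 were renamed through a synonym that belongs to 1 gene, 10473 kept the name of the array and 27 had names that a spreadsheet had turned into dates. A gene with several probes was represented by the probe with the highest mean over all 5 arrays, which left 15733 genes. Further probes of the genes named by the rule were compared with the probe used.

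Differences between Dicer cKO and control pools were tested with limma (lmFit, and eBayes with an intensity trend) with no covariate, 2-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 over all 15733 genes are called. An exact permutation test was not used, since 5 pools allow 10 splits and no 2-sided share below 0.1. Differences are Dicer cKO minus control on the log2 scale with the standard error of the fit. The offset compresses differences of dim genes. For a gene not detected on any array of a group, the fold is a lower bound, computed against the group mean of the higher of the lowest detected signal of each array and the gene's own signal. A gene counted as detected where any of its probes was, so where only the probe used fell below detection, no bound was set. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation and with fry beside it, adjusted over 37 lists. Camera compares a list with all other genes, while fry tests whether the genes of a list move, on balance, one way and does not compare them with other genes.

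The gene lists, the tests, the filters, the alternatives and the rule for the genes named were fixed before the data were examined, except where stated. The rule named Dicer1, Pgr and Esr1, the 12 genes with the largest increase and the 12 with the largest decrease among called genes whose groups did not overlap and that have a proper gene symbol, and up to 4 called members of each list with the largest difference, or 2 members by moderated t where none was called; not every gene it named is printed. Other members named below were chosen after their values were seen. No slide or scan information was found in the labels or files, so no batch could be tested. Whether any pair of arrays held the same library was checked with the bead-to-bead error. The squared difference over its bead variance had a median between 1.30 and 1.82 within groups, against 0.455 if bead error were the only difference. A library hybridised more than once could differ by more than bead error, so the check cannot exclude one. All 5 arrays were counted as separate pools, as labelled.

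The fit was tested on simulated data with the spread of these arrays, with 200 of 15733 genes changed, in 5 runs. The simulated genes varied independently and with the same spread in both groups, so the rates need not hold for the real arrays. It recovered 24.4% of genes changed by 0.5 log2, 94.4% of those changed by 1, 98.8% of those changed by 1.5 and 99.6% of those changed by 2, and 5.82% of the calls were false. The number of arrays limits the precision. Alternatives covered the background correction, the normalization, the detection filter, the moderation of the spread, array weights, the choice of probe, the threshold, the offset, the set test and each pool left out in turn.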

Results

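The arrays compared whole uteri of young mice lacking Dicer in cells that express the progesterone receptor with uteri of control mice, at 15 days of age. There were 3 control pools and 2 Dicer cKO pools, each read on 1 array. Between 47.0% and 49.5% of 45281 probes were detected on an array, with 21297 probes on Dicer cKO pool 10 at the low end and 22414 on control pool 7 at the high end. Across 15733 genes, the correlation of log2 signals was 0.993 between the Dicer cKO pools and between 0.993 and 0.994 among the control pools. Between the groups it ran from 0.978 to 0.989. The median absolute log2 difference was 0.148 between the Dicer cKO pools. It was similar, at 0.148 and 0.149, between Dicer cKO pool 12 and control pools 9 and 11. The largest principal component held 62.6% of the variance and separated the groups.

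Dicer1 itself was modestly lower in the Dicer cKO pools. Its brighter probe, listed on the array under the older name D12Ertd7e, read 9.15, 9.08 and 9.12 log2 units in control pools 7, 9 and 11 and 8.62 and 8.75 in Dicer cKO pools 10 and 12, a difference of -0.43 ± 0.09 (SE; limma adjusted p = 0.0224). The dimmer probe differed by -0.22 ± 0.13 and was not called. Where these probes lie relative to the deleted part of the gene is not given in the sources used here, and PR-Cre acts only in cells that express the progesterone receptor, so the values are a weak check of the labels. The call was lost without control pool 7, 9 or 11, without Dicer cKO pool 10, and without the intensity trend, with limma adjusted p from 0.0526 to 0.180. Pgr, the gene of the progesterone receptor and the locus that carries Cre, fell by 0.77 ± 0.14 (limma adjusted p = 0.0090), a call lost without Dicer cKO pool 10 (limma adjusted p = 0.113). The labels call the controls wild type. Whether they carried Cre or floxed alleles is not given in the sources used here, so effects of the Cre insertion are not separated from those of Dicer loss in any difference. Esr1, the oestrogen receptor, differed by -0.12 ± 0.09 and was not called.

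Large differences between Dicer cKO and control uteri went both ways. On the log2 scale, Fxyd4, a regulator of the sodium pump, changed by -4.04 ± 0.45, the secreted phospholipase gene Pla2g10 by -3.46 ± 0.34 and Lrp2, an endocytic receptor, by -3.29 ± 0.35. Aldh1a3, an enzyme that makes retinoic acid, rose by 3.53 ± 0.10, an 11.6-fold difference between means of 7.27 and 10.80. The late cornified envelope gene Lce3c, listed on the array as Sprrl1, rose by 3.16 ± 0.18, the tight junction gene Cldn6 by 3.06 ± 0.13 and the keratin gene Krt17 by 2.60 ± 0.12. In all, 1061 genes were called by limma, 438 higher and 623 lower in Dicer cKO uteri, and among those with a difference of at least 1 log2 unit 65 were higher and 173 lower.

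Further genes among the 12 largest increases were Gpnmb (3.34 ± 0.20), a glycoprotein of lysosome-rich cells, the Kazal-type protease inhibitor Spink8 (2.96 ± 0.14), the RNA-binding protein gene Igf2bp3 (2.48 ± 0.14, with 2.69 and 0.61 from dimmer probes), the keratin gene Krt90 (2.45 ± 0.17), Elmod1 (2.22 ± 0.17) and Cdkn1a (2.20 ± 0.12), an inhibitor of cyclin-dependent kinases. Lce3b and the gap junction gene Gjb6 were not detected on any control array and were at least 3.70-fold and 3.47-fold higher in the Dicer cKO pools. Lce3b and Lce3c belong to a family of near-identical genes, whose transcripts their probes were not tested to tell apart. Among the 12 largest decreases, the chloride channel regulator Clca1, listed as Clca3, stood at -3.46 ± 0.25, Elapor1 at -3.04 ± 0.21, the lipogenic gene Thrsp at -2.98 ± 0.24 and the zinc transporter gene Slc39a4 at -2.97 ± 0.29. They were followed by the chemokine gene Cxcl15 (-2.70 ± 0.20), the sulfotransferase gene Sult1d1 (-2.68 ± 0.41), Fxyd3 (-2.61 ± 0.18) and the oviductal glycoprotein gene Ovgp1 (-2.57 ± 0.39). Mia, a secreted protein gene, was not detected on either Dicer cKO array and was at least 6.65-fold lower there. Second, dimmer probes of Gpnmb and Sult1d1 differed by -0.12 and -0.08 and were not called. The probe used for Clca1 was dim in Dicer cKO pools 10 and 12, at 4.68 and 4.85. A second probe of Clca1 differed by -2.63 and was called. It replaced the first without control pool 7 or 11, where Clca1 differed by -2.91 and -2.46.

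**Figure D1:**
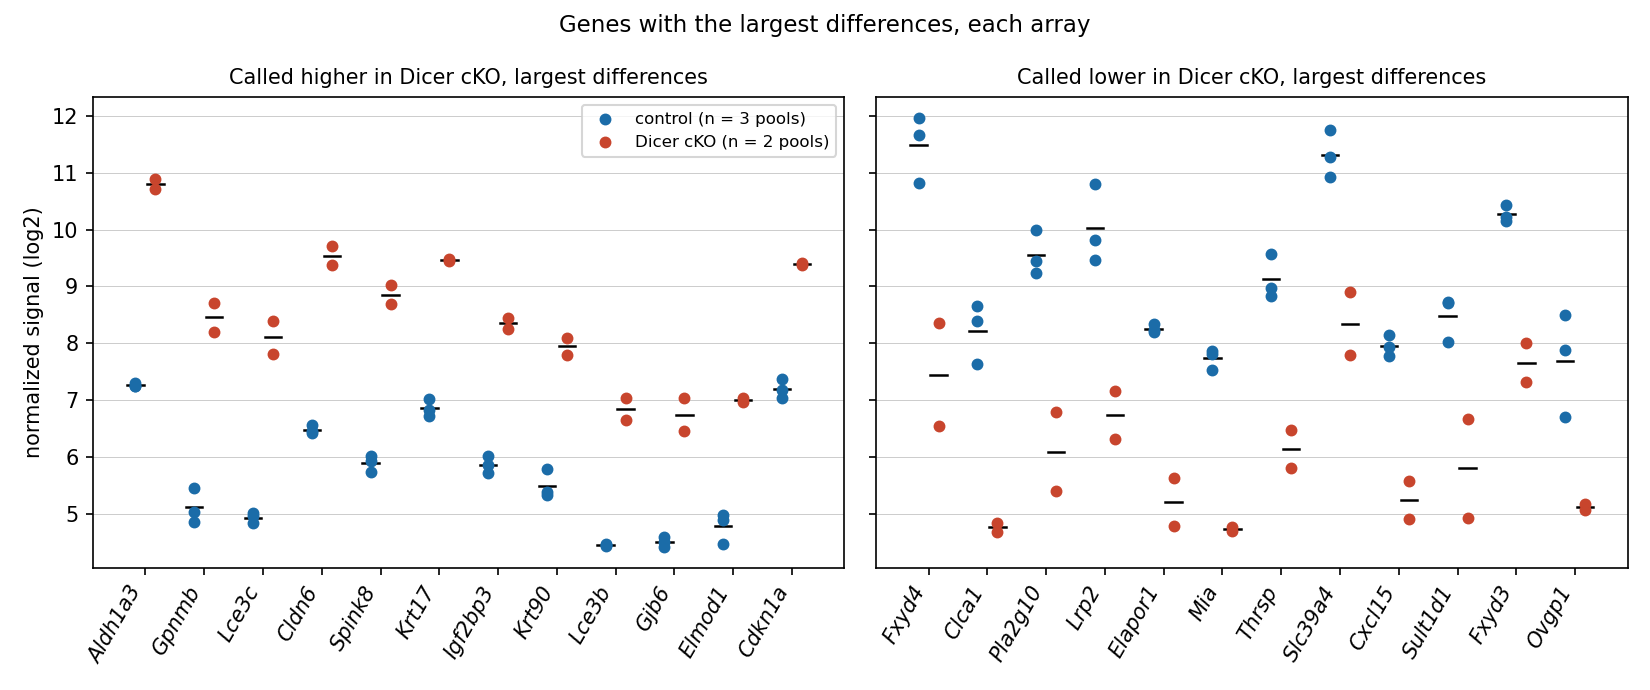
Normalized log2 signal of each of the 5 arrays for the 12 genes with the largest increases (left) and the 12 with the largest decreases (right) in Dicer cKO uteri. Points are pools (3 control in blue, 2 Dicer cKO in red) and bars are group means; Aldh1a3 averages 7.27 in control and 10.80 in Dicer cKO pools, and Fxyd4 11.48 and 7.45.

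For every 1 of the 1061 called genes, both Dicer cKO arrays lay on the same side beyond all control arrays, as they did for 5912 of all 15733 genes (37.6%, where chance alone gives 20%). At an unadjusted p under 0.05, 3266 genes differed. The count of called genes fell to 275 without Dicer cKO pool 10, to 606 without control pool 7 and to 644 without control pool 9. With a robust estimate of the spread in limma, the calls of Fxyd4, Lrp2, Slc39a4, Sult1d1 and Ovgp1, whose signals differed strongly within a group, were lost, with adjusted p from 0.0534 to 0.128. Ovgp1 was also not called without Dicer cKO pool 10 (limma adjusted p = 0.0600), nor Sult1d1 under a filter that kept only its dimmer probe.

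Several genes linked to uterine glands fell. Of 12 measured, 6 fell, none rose and 6 did not pass, and 7 were lower when adjusted over the list alone. Besides Cxcl15, the claudin gene Cldn10 fell by 2.23 ± 0.12, the Wnt-responsive receptor gene Lgr5 by 0.95 ± 0.10 and the transcription factor gene Sox17 by 0.87 ± 0.13. The list had a median of -0.46 (camera adjusted p = 1.8e-08 in limma; adjusted p = 0.614 with an estimated correlation). General epithelial markers went both ways at the same time. Of 31 measured, 7 rose and 9 fell, with Prom2 at 2.08 ± 0.18 and Sprr2f at 1.04 ± 0.13 among those that rose, and Cldn3 at -1.48 ± 0.17 and Rab25 at -1.20 ± 0.09 among those that fell. The simple-epithelium keratin genes Krt18, Krt19 and Krt8 fell by 0.86, 0.54 and 0.37, while Krt7 rose by 0.57. The epithelial list as a whole had a median of -0.03 (camera adjusted p = 0.597 in limma), with 9 higher and 13 lower adjusted over the list alone.

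More of the steroid receptors and their uterine targets were lower than higher, but fry did not call the list (fry adjusted p = 0.106). Of 25 measured, 6 fell, 3 rose and 16 did not pass, against 7 lower and 4 higher adjusted over the list alone. Beside Clca1 and Lrp2, Ihh, the hedgehog ligand of the uterine epithelium, fell by 1.96 ± 0.25 and Ltf, encoding the secreted protein lactoferrin, by 1.44 ± 0.25. The median was -0.21 (camera adjusted p = 0.0298 in limma; adjusted p = 0.614 with an estimated correlation). The Hedgehog list, which shares Ihh, had 3 genes lower of 12 measured, also 3 adjusted over the list alone, among them Ihh and the receptor gene Ptch1 (-1.33 ± 0.19). Its median was -0.10 (camera adjusted p = 0.039 in limma; adjusted p = 0.614 with an estimated correlation). The steroid list lost its camera call in 3 of 13 settings, without Dicer cKO pool 10 (camera adjusted p = 0.169), with detection required on all arrays (0.165) and with no detection filter (0.0571). The Hedgehog list lost it in 5 of 13, with detection required on all arrays (0.317), without Dicer cKO pool 12 (0.0751) or control pool 11 (0.0524), with an offset of 50 (0.0528) and without background correction (0.0507).

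Of 38 cell division genes measured, 10 rose, none fell and 28 did not pass, while 31 were higher adjusted over the list alone. The cyclin gene Ccne1 rose by 1.16 ± 0.18, the replication gene Mcm5 by 0.69 ± 0.16, the mitotic kinase gene Aurka by 0.67 ± 0.13 and Ccne2 by 0.65 ± 0.16. The median was 0.46 (camera adjusted p = 7.4e-12 in limma at the preset correlation). With the estimated correlation, which was 0.743 for this list, the camera adjusted p was 0.689. Fry did not call the list (fry adjusted p = 0.223). Camera values with a pool left out also rest on the preset correlation. The number of called members depended on single pools, at 0 without Dicer cKO pool 10, 1 without control pool 7, 3 without control pool 9 and 24 without Dicer cKO pool 12, while the camera adjusted p stayed at or below 7.3e-06. Among p53 targets and apoptosis genes, 4 of 27 rose and 2 fell (6 and 2 adjusted over the list alone), with Cdkn1a, Bcl2l11 (1.02 ± 0.11), Pmaip1 (0.83 ± 0.15) and Gtse1 (0.75 ± 0.15) higher. Their median was -0.01 with a mean of 0.13, and the list did not pass (camera adjusted p = 0.597 in limma).

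Targets of the let-7 microRNAs were the microRNA target list with a camera call. Of 29 established targets measured, 11 rose, 1 fell and 17 did not pass, with 11 and 2 adjusted over the list alone. Igf2bp3 led, followed by the chromatin protein gene Hmga1 (1.02 ± 0.17, with a dimmer probe at -0.21 that was not called), Arid3a (0.95 ± 0.16) and Nr6a1 (0.86 ± 0.13); the member that fell was Dicer1. The median was 0.09 (camera adjusted p = 0.0164 in limma; adjusted p = 0.614 with an estimated correlation). Without Dicer cKO pool 10 the list had 3 members higher, and its camera call was lost without Dicer cKO pool 12 (camera adjusted p = 0.134) and with detection required on all arrays (0.0876). Of 32 targets of the miR-17 family, 3 rose and 1 fell (4 and 1 adjusted over the list alone), among them Cdkn1a, Bcl2l11 and the cyclin gene Ccnd1 (0.54 ± 0.09), with Txnip at -0.54 ± 0.10. Of 28 miR-29 targets, Tdg (0.56 ± 0.12) and Dnmt3b (0.53 ± 0.11) rose and Lox (-0.61 ± 0.13) and Mmp2 (-0.28 ± 0.07) fell, with 2 and 3 adjusted over the list alone. Of 22 targets of miR-143 and miR-145, Hk2 rose (1.15 ± 0.13) and Klf5 fell (-0.77 ± 0.10), with 2 and 3 adjusted over the list alone. Of 16 miR-21 targets, Cdc25a rose (0.59 ± 0.11) and Rasgrp1 fell (-1.57 ± 0.26), with 1 and 3 adjusted over the list alone. Among 24 targets of the miR-200 family 0 were called by limma, also adjusted over the list alone, with Fn1 at 0.31 ± 0.09 and Jag1 at -0.40 ± 0.13. These 5 lists had camera adjusted p from 0.299 to 0.672 in limma.

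Components of the small RNA machinery other than Dicer1 were higher where they were called. Of 15 measured, 4 rose and 1 fell, the same counts as adjusted over the list alone, with Lin28a, which blocks let-7 maturation, at 0.67 ± 0.13, Ago2, the slicing Argonaute, at 0.65 ± 0.08 and Tarbp2, a partner of Dicer, at 0.48 ± 0.11. Camera did not call the list (median 0.10, camera adjusted p = 0.176 in limma), while fry did (fry adjusted p = 0.0297). No member of the list was called without Dicer cKO pool 10, and the call of Ago2 depends on the probe: its 3 probes differed by 0.65, 0.44 and 0.29, and only the first was called. Leaving out Dicer cKO pool 10 or 12 put the probe with the lowest difference in place of the first, at 0.28 and 0.30, and Ago2 was then not called.

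More Wnt pathway genes were higher than lower, but fry did not call the list (fry adjusted p = 0.0977). Of 39 ligands, receptors and modulators, 8 rose and 1 fell (11 and 2 adjusted over the list alone). The ligand genes Wnt4, Wnt10a and Wnt7b rose by 1.52 ± 0.19, 1.21 ± 0.16 and 1.18 ± 0.24, and the feedback inhibitor gene Notum by 1.23 ± 0.13, while Lgr5 fell. The median was 0.08 (camera adjusted p = 0.039 in limma; adjusted p = 0.614 with an estimated correlation). The camera call was lost without control pool 9 (camera adjusted p = 0.112), without Dicer cKO pool 12 (0.357) and with no detection filter (0.0533). In the retinoid pathway, Aldh1a3 and the retinol uptake receptor gene Stra6 (1.47 ± 0.11) rose and the other 13 genes did not pass, with 2 higher adjusted over the list alone (median -0.02, mean 0.28, camera adjusted p = 0.597 in limma). Fry, unlike camera, called the retinoid list (fry adjusted p = 0.0297). Among 33 BMP and TGF-beta genes, Inhbb, an activin subunit, rose by 1.49 ± 0.28 and Tgfbr1 by 0.50 ± 0.08, while Tgfbi (-0.74 ± 0.08) and Bmp4 (-0.58 ± 0.11) fell, with 3 and 2 adjusted over the list alone. Of 26 Müllerian duct patterning factors, 1 fell, Amhr2, the receptor of the anti-Müllerian hormone (-0.83 ± 0.12), also 1 adjusted over the list alone. None of 15 Notch pathway genes was called by limma, also adjusted over the list alone, with Heyl at -0.40 ± 0.13 and Jag1 at -0.40 ± 0.13 (camera adjusted p = 0.141).

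Of 34 IGF and FGF growth factor genes, 4 rose and 2 fell (5 and 9 adjusted over the list alone), among them Igf1 (0.55 ± 0.09), Igfbp2 (0.68 ± 0.18, lost in 9 of 14 settings) and Igfbp6 (-0.98 ± 0.18), and Fgf9, not detected on any control array, was at least 1.23-fold higher. Of 16 imprinted fetal growth genes, Nnat (1.52 ± 0.17) and Igf2r (0.47 ± 0.08) rose, with 7 higher and 1 lower adjusted over the list alone. Among 41 fibrillar collagen and matrix genes, 2 rose and 5 fell (3 and 7 adjusted over the list alone), with Lama1 at 0.69 ± 0.16, Tnc at -0.72 ± 0.16, Lox and Lama2 at -0.53 ± 0.12. These counts depended on single pools, Dicer cKO pool 10 among them. With a control pool left out, 0 rose and 1 fell without pool 7, 0 and 2 without pool 9, and 3 and 0 without pool 11. Of 25 chemokine and cytokine genes, 2 rose and 3 fell (2 and 4 adjusted over the list alone), with Cxcl14 at 1.34 ± 0.12, Il34 at -0.83 ± 0.15, Ccl11 at -0.55 ± 0.11 and Cxcr4 at -0.54 ± 0.13. Of 21 immediate early genes, Fosl2 rose (0.42 ± 0.10, lost in 9 of 14 settings) and Ier3 fell (-0.58 ± 0.12), with 2 and 3 adjusted over the list alone, and of 28 interferon response genes Oasl1 rose (1.30 ± 0.16), also 1 adjusted over the list alone. The camera adjusted p of these 6 lists, of the BMP and TGF-beta list and of the patterning factors lay between 0.141 and 0.969 in limma.

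Markers of other cell types moved to different extents. Of 11 adipocyte markers measured, 4 were lower and none higher (6 lower adjusted over the list alone), with Adipoq at -1.42 ± 0.30, Cfd at -1.38 ± 0.34, Dgat2 at -0.52 ± 0.11 and Thrsp, which epithelial cells can also express (median -0.52, camera adjusted p = 0.0018 in limma; adjusted p = 0.714 with an estimated correlation). The adipocyte list was not called by fry (fry adjusted p = 0.273), and its estimated correlation was 0.732. Adipoq and Cfd were not called without Dicer cKO pool 10 or with a robust spread, among other settings. Of 28 stromal markers, 5 fell and none rose (8 lower adjusted over the list alone), with Vim at -0.82 ± 0.12, Thy1 at -0.79 ± 0.11, Twist2 at -0.70 ± 0.08 and Tcf21 at -0.33 ± 0.08, a call lost in 9 of 14 settings (median -0.08, camera adjusted p = 0.0267 in limma; adjusted p = 0.614 with an estimated correlation). Nor did fry call the stromal list (fry adjusted p = 0.0977). The stromal call was lost without Dicer cKO pool 10 (camera adjusted p = 0.0934) and without control pool 11 (0.109). More myeloid markers were higher than lower, with 5 of 21 called higher and 1 lower (8 and 1 adjusted over the list alone). Fry did not call the list (fry adjusted p = 0.401). The lysozyme genes Lyz2 and Lyz1, near-identical copies, rose by 0.83 ± 0.13 and 0.79 ± 0.12 and the lysosomal protein gene Cd68 by 0.81 ± 0.13, while Cd14 fell by 1.81 ± 0.18 (median 0.29, camera adjusted p = 0.0215 in limma; adjusted p = 0.838 with an estimated correlation). That call was lost without control pool 9 (camera adjusted p = 0.0868) and without Dicer cKO pool 12 (0.564).

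Of 36 smooth muscle contractile genes, Ppp1r14a rose (0.40 ± 0.09) and Hspb1 fell (-0.67 ± 0.15), also 1 and 1 adjusted over the list alone, and the list median was 0.05 (camera adjusted p = 0.821 in limma). Of 11 skeletal muscle markers, Tnni2 (0.87 ± 0.11) and Atp2a1 (0.53 ± 0.13) rose and Acta1 fell (-0.69 ± 0.13), with 2 and 2 adjusted over the list alone. Among 21 endothelial markers Vwf fell (-0.59 ± 0.13), and among 6 mast cell markers Hdc fell (-2.13 ± 0.39), a histamine-making enzyme that uterine epithelium can also express; the call of Hdc was lost without Dicer cKO pool 10 and with a robust spread. Of 9 erythrocyte genes Tfrc rose (0.79 ± 0.14), of 13 mesothelial markers Cldn15 rose (0.46 ± 0.10) and Krt19 fell, of 10 nerve and Schwann cell markers Mal rose (0.75 ± 0.13), and of 7 ovary and oviduct genes Ovgp1 fell. Each of these 6 lists had the same number of called members adjusted over the list alone. None of 12 lymphocyte markers and 6 bladder urothelium genes was called by limma, also adjusted over the list alone, with Cd3g at -0.35 ± 0.17, Jchain at 0.28 ± 0.16 and Upk1a at -0.23 ± 0.16. The camera adjusted p of the lists from skeletal muscle to bladder lay between 0.164 and 0.969 in limma.

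**Figure D2:**
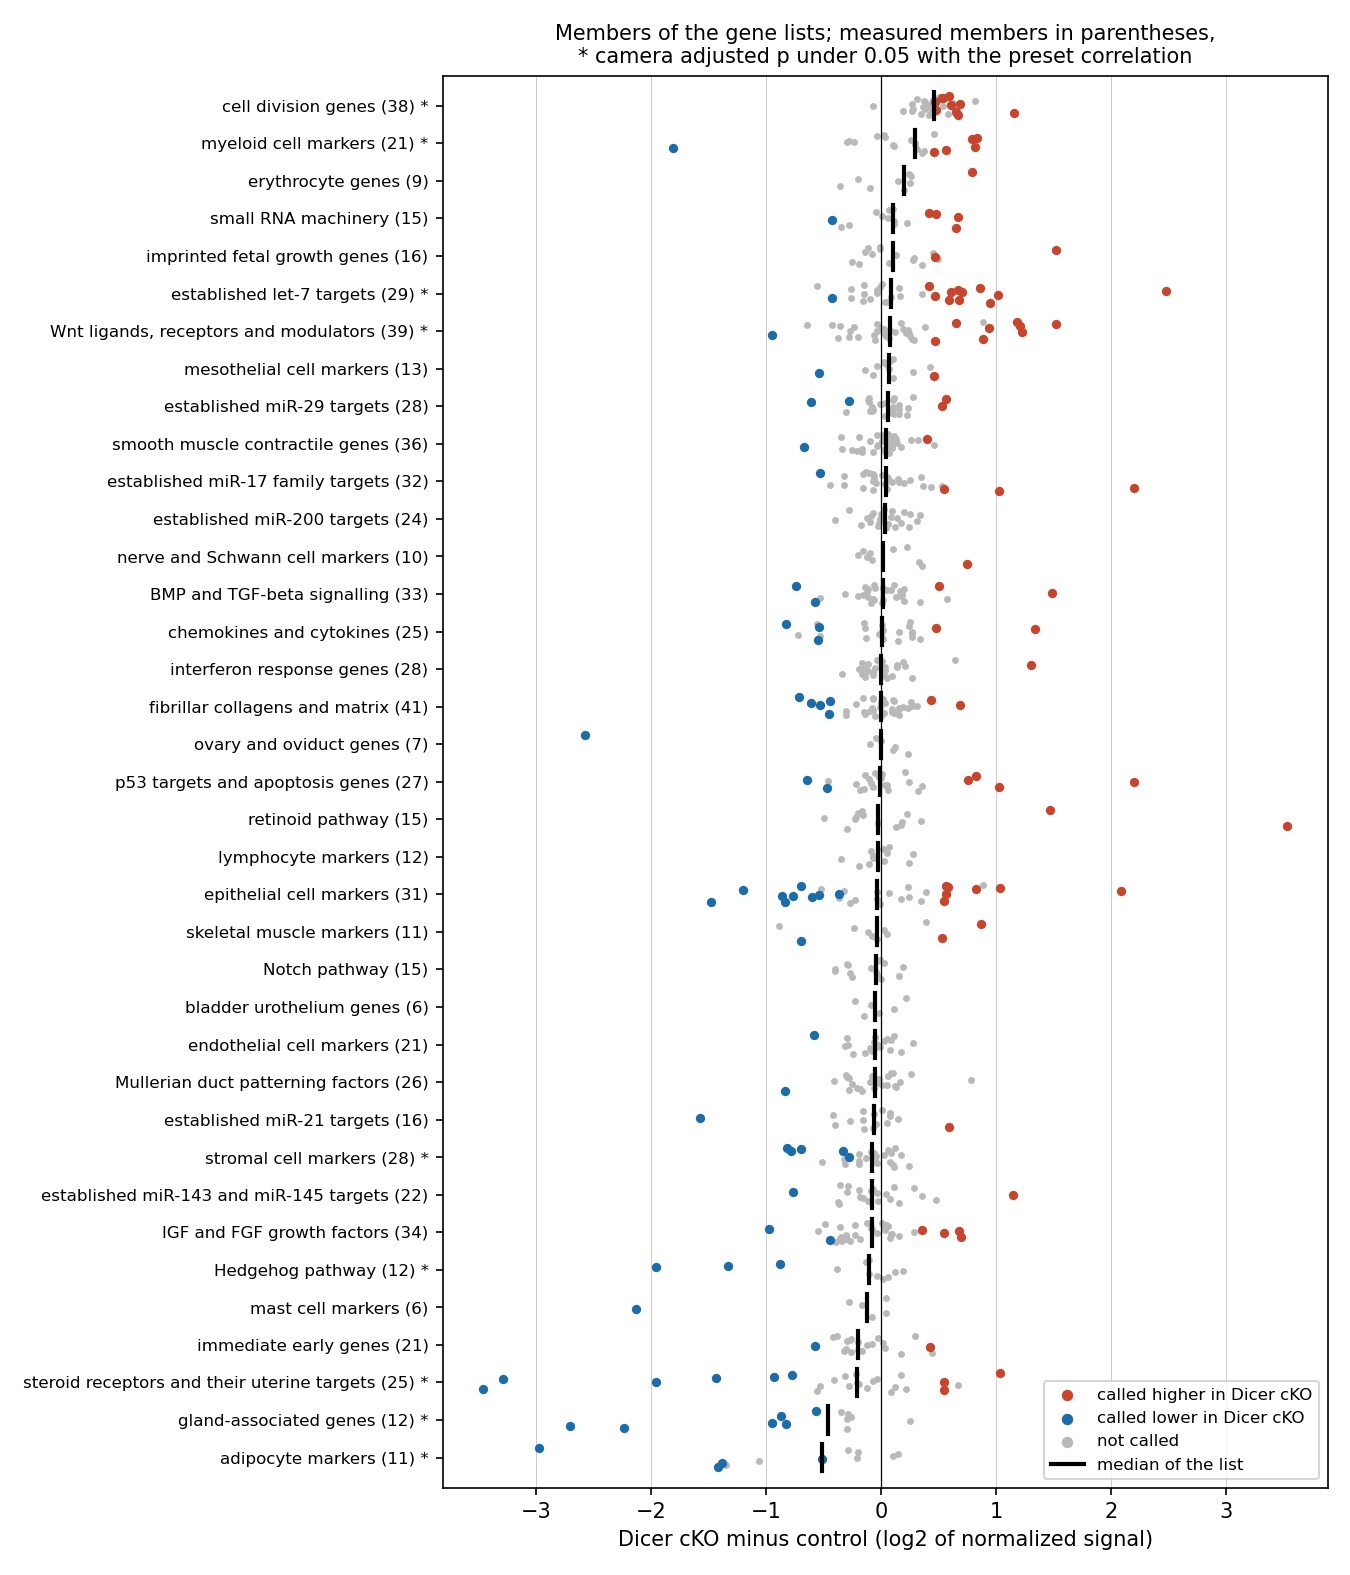
Difference in log2 signal, Dicer cKO minus control, of each measured member of the 37 lists, with called genes in colour and the median of each list as a black bar. Gland-associated genes (median -0.46) and adipocyte markers (median -0.52) lie lowest, and cell division genes (median 0.46) highest.

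Of the 116 genes named by the rule, 44 had more than 1 probe past the filter. No further probe was called in the opposite direction when probes were tested singly in limma, but for 18 called genes a further probe was not called: Dicer1, Gpnmb, Sult1d1, Ago2, Amhr2, Bcl2l11, Ccl11, Cdc25a, Cldn15, Gtse1, Hmga1, Igf1, Mal, Ppp1r14a, Ptch1, Tarbp2, Tgfbr1 and Tnc. The further probe of Ppp1r14a differed by 0.01. Of the further probes of Tnc, the dimmer differed by 0.08 and was not called, and the other by -0.67 and was called. Of the 108 called genes named by the rule, some were not measured in every setting. Lce3b and Gjb6 were measured in 11 of 14, and in neither setting that left out a Dicer cKO pool. Of the 108, 51 kept their call wherever they were measured and 41 lost it in 1 to 4 settings. The other 16 lost it in 5 or more of 14: Tcf21, Igfbp2, Fosl2, Atp2a1, Mmp2, Tarbp2, Cfd, Ppp1r14a, Ccne2, Cxcr4, Lama2, Cldn15, Dgat2, Dicer1, Mcm5 and Vwf.

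Camera with its preset correlation called 9 of the 37 lists, 4 higher and 5 lower in Dicer cKO uteri, and with an estimated correlation 0, with the smallest adjusted p at 0.614. Fry called 5 lists, of which let-7 targets, Hedgehog and gland-associated genes were also called by camera, and the small RNA machinery and retinoid lists were not. With 5 pools the correlation within a list is poorly estimated, and the calls by camera rest on the preset value.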

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

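The comparisons of unfiltered probes with the authors' normalized table, at the end, were chosen after the data were seen, and all other alternatives were planned. No named gene and no list passed the threshold in 1 direction and took the other direction under an alternative, but the medians of 17 of the 28 lists that camera did not call changed sign in at least 1 setting, against 0 of the 9 called. An adjusted p under 0.10 gave 1625 called genes, of which 746 were higher, and a required difference of at least 1 log2 gave 238, of which 65 were higher and 173 lower, as the construction of these thresholds implies. Without the detection filter, which raised the genes tested to 29527, 745 genes were called, of which 286 were higher. Without the intensity trend in limma 735 were called, of which 281 were higher, and the cause was not tested. Leaving out a pool in turn gave totals from 275 to 956, with 86 to 403 higher and 189 to 553 lower. The lowest values came without Dicer cKO pool 10, where 265 of the 275 genes were also called with all pools, and where, as without pool 12, the lone cKO pool is assumed to vary like the control pools. Without control pools 7 and 9 the totals were 606 and 644. Quantile normalization without background correction, array medians alone, array weights, a robust spread, a stricter filter, probes tested singly and an offset of 50 kept the total between 781 and 1099, with no gene called in the opposite direction. For the gene lists, camera gave 6 to 10 calls over the other settings and 7 to 9 with a pool left out, but 0 with an estimated correlation and 5 when replaced by fry; camera and fry test different hypotheses. Of the 116 genes named by the rule, 52 of the 113 measured without Dicer cKO pool 10 moved to the other side of the threshold, as did 26 without control pool 7, 21 without control pool 9 and 21 without the intensity trend. No paired analysis was possible because the groups share no pool number. The authors' normalized table could not be run for named genes or lists, since its rows could not be matched to genes; at the level of unnamed, unfiltered probes it gave 1295 called probes, against 1036 from the array files and 1319 from these with quantile normalization and no background correction. Signal over background limits the dimmest genes: among called genes, 30 of those higher were not detected on any control array and 55 of those lower on neither Dicer cKO array, so their folds are lower bounds.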

Other observations

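All tests in this part were chosen after the results were seen, as were the genes and the 2 added gene lists named here, and the decision rules for oviduct tissue, for loss of glands and for stratified epithelium were rewritten, and the tests for control-like tissue and for an axis shared with the control pools replaced, after their first results were known.

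Of 14 claudin genes measured, which set the permeability of epithelial tight junctions, 3 rose (Cldn6, Cldn4 and Cldn15) and 5 fell in Dicer cKO uteri. Cldn23, Cldn3, Cldn1 and Cldn22 fell by 1.88, 1.48, 1.42 and 1.41 on the log2 scale along with Cldn10, and with array medians alone 1 rose and 5 fell. Of 6 cytosolic sulfotransferase genes, 4 fell and 1 rose: Sult2b1 fell by 1.19 and Sult1a1 by 1.02 beside Sult1d1, Sult1c2 was not detected on either Dicer cKO array and was at least 2.50-fold lower, and Sult4a1 was higher by 1.16. With array medians alone 3 fell and 1 rose. The probe used for Sult2b1 was dim in Dicer cKO pools 10 and 12, at 4.87 and 4.66. The alpha-1 antitrypsin genes Serpina1b, Serpina1d and Serpina1e, near-identical copies whose probes cannot be told apart here, differed by -1.63, -1.79 and -1.55. They are among the 50 measured genes nearest to Dicer1 on either side, and on this mixed background a difference in the strain origin of that region was not tested.

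Among genes that macrophages express, Trem2 rose by 0.96 and Cd68 by 0.81, Spp1, not detected on any control array, was at least 2.88-fold higher, and Cd14 fell by 1.81. The myeloid list as a whole did not keep its call with an estimated correlation (camera adjusted p = 0.838 in limma). Of the transcription factor genes, Elf5, Sox11 and Sox4 rose by 0.98, 0.58 and 0.49, Tfap2a, not detected on any control array, was also called higher, and Barx2 fell by 1.68. The gap junction gene Gjb2 rose by 1.90 beside Gjb6, and the keratin gene Krt12 fell by 1.80.

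The fall of gland-associated genes was weighed against a change in tissue makeup. A smaller share of epithelial cells as the whole cause would lower epithelial markers in general, but 7 of 31 were called higher and 9 lower. A smaller share as a part of the cause stays open. Oviduct tissue in the control pools would bring ciliated cells. The 10 ciliated cell genes measured had a median of -0.15, with 3 above 0 and 7 below, and 1 called lower, Tppp3 (-0.70). Foxj1, the transcription factor gene of ciliated cells, differed by 0.12 ± 0.14 and was not called. This explanation stays open, since several of the 10 genes were dim and others are expressed in many cells. A loss of glands may account for the 6 of 12 gland-associated genes that fell. It cannot be separated from a change within the glands or the luminal epithelium in whole uteri. Among those that fell, the gland factor Foxa2 was dim, at a mean of 5.17 in the control pools. Foxa2 was not detected on either Dicer cKO array and was at least 1.12-fold lower there. An effect of Dicer loss on epithelial differentiation stays open and was not tested.

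Other cornified envelope genes that lie near Lce3c and Lce3b rose as well. Of 9 measured genes between S100a9 and S100a11 in the gene table, 5 were called higher (Lce3c, Lce3b, Ivl, Crct1 and Sprr2f) and 1 lower (Lor), a group singled out because Lce3c and Lce3b rose, so that Fisher's exact test of its count, run on the same genes, decides nothing. A transcript read by several near-identical probes would stay within 1 family, whereas the genes called higher came from 4. Stratified epithelium taken along from vagina, cervix or skin stays open. A list of 12 of its genes had a median of -0.19, with 1 called higher (Sfn) and 4 lower (Itgb4, Lor, Col17a1 and Krt10). Krt5 stood at 0.12 ± 0.20 and Trp63 at -0.39 ± 0.15. The list left out Krt17, Krt90, Gjb6 and Gjb2, which rose. With these added, 5 of 16 were called higher and 4 lower, and the median was 0.06, so the list does not decide. An effect of Dicer loss on the uterine epithelium also stays open and was not tested.

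The Dicer cKO pools differed from each other: pool 10 lay further from the control mean than pool 12 for 76.0% of the called genes. If pool 12 held some control-like tissue, every gene would imply the same share, and genes with a difference of over 1 log2 implied a median of 22.2% where called higher and 11.2% where called lower, a ratio of 1.98. Their quartiles overlapped (2.79% to 32.5% and 3.83% to 18.0%), so this explanation stays open; that 96.9% and 91.9% of the estimates lay within 2 standard errors of their median says little, because that error already contains the difference between these pools. An axis of variation that also separates the control pools, such as the stage of development or the makeup of the tissue, stays open as well. The difference between pools 12 and 10 correlated with that between control pools 7 and 11 at r = 0.48 across called genes, which mixes genes that rose with genes that fell, but at 0.20 within those called higher, 0.36 within those called lower and 0.17 among genes not called, and less with the other control pairs.

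Genes close to the targeted loci were not called more often, with 13 of 168 among up to 50 nearest measured genes on each side of Dicer1 and Pgr (7.74%) against 7.80% of other genes. Of the 8 called near Dicer1, 7 fell, among them Degs2 (-1.54) and the 3 Serpina1 genes, whose probes cannot be told apart here. Of the 5 near Pgr, 4 rose and 1 fell. Among all 1061 called genes 623 fell, and the direction near the loci was not tested. The 5 pools allow 10 splits into 3 and 2, too few for a share under 0.05: the real split called 1061 genes by limma, and was the only 1 to reach that count, with the highest of the others at 1.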
